A study of Homo sapiens with 4 samples.

How the data were processed

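Messenger RNA was measured in human macrophages in 4 libraries, 1 for each condition. CD14-positive blood cells were grown for 1 day with macrophage colony-stimulating factor (MCSF) at 10 ng/mL, which turns monocytes into macrophages. Transwell inserts, which keep cell layers apart while secreted molecules pass, were then set above the macrophages, either empty or carrying human synovial fibroblasts (the connective tissue cells of the joint lining) of passage 4 or later. Cultures received tumour necrosis factor (TNF) at 20 ng/mL or none for 2 days, and the macrophage layer was harvested. The 4 groups follow from the labels as a 2 by 2 layout of fibroblasts and TNF. The sources used here do not say whether the 4 cultures came from the same donor.

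Per the labels' protocols, polyadenylated RNA was made into libraries with a TruSeq kit, and the series' design text states about 75 M reads for each sample, read for 50 cycles from 2 ends. Alignment with TopHat to hg19 and transcript abundance with Cufflinks are given per the submitters' processing notes and the design text, and the versions are not given in the sources used here. The values the authors deposited are FPKM, which are fragment abundances scaled by transcript length and library size, written to 2 decimals. The table holds 37436 RefSeq transcripts under 23134 symbols, of which 7256 have more than 1 transcript. It contains 0 mitochondrial genes under the usual MT- symbols. Because Cufflinks estimates abundance from fragments shared between transcripts, the values show no steps of whole reads, so the depth behind each value is unknown and no counting interval can be given. The upper quartiles over transcripts lay between 26.97 and 27.16 in the 4 libraries, and the sources used here do not say whether a scaling step made them alike. An exact 0 can be a failed estimate: 27 genes were listed at 0 in the TNF library but at 5 FPKM or more in the other 3 libraries, against 16, 10 and 4 such genes in the libraries of macrophages alone, of co-culture, and of co-culture with TNF. Such genes are described as listed at 0, with no fold.

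For 59 transcripts whose symbols (26 in all) had been turned into calendar dates, the symbol was restored through the RefSeq accession. Genes on the Y chromosome, XIST and TSIX were left out. Each gene was represented by its transcript with the highest mean FPKM over the 4 libraries. Its value is therefore that of a single transcript, so a shift of estimated abundance between transcripts of a gene can look like a change of the gene. The sum over all transcripts was computed as an alternative and is given beside the printed difference of a called gene, or the median of a list, where it ends a call, turns its direction or moves its value by over 1.5 times. Genes were kept if their highest FPKM over the 4 libraries was at least 1, which left 13686. Differences are of log2(FPKM + 1), a scale that understates the change of genes with low values. A gene was called higher or lower when its difference reached 1 in size, a 2-fold difference on that scale. With 1 library per group this is a rule of size and not a test, and no difference has a replicate check or is given a p-value or an error. The 5 comparisons were TNF against none in macrophages alone, fibroblasts against none without TNF, fibroblasts against none with TNF, TNF against none in co-culture, and the difference between the TNF effects with and without fibroblasts.

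A total of 40 gene lists, 29 of pathways and 11 of cell type markers, were scored by the median difference of their measured members and by its percentile among 10000 random lists of the same size, drawn from 10 bins of mean expression. A list is said to stand apart at a percentile of at most 2.5 or at least 97.5, which describes these libraries only. Named genes were, for each comparison, the 10 with the highest and the 10 with the lowest difference among genes at 5 FPKM or more in either library of the comparison (in any library for the difference of effects), up to 4 members of each described list with the largest difference, and a fixed set of TNF, interferon, prostaglandin, scavenger and fibroblast genes. Genes with common copy-number deletions or haplotype-specific copies, antigen receptor segments, unnamed loci and short RNA genes were excluded from the ranking. A few genes that met the rule are not reported here. The groups, comparisons, lists, naming rule and alternatives were chosen before the data were examined, except for the correction for transcript length and GC content, which was added afterwards. The use of the most abundant transcript was also written down before, but sums over transcripts were the main value for part of the work, and the return to the written rule came after both sets of results had been seen.

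Comparisons that share the TNF library are related by chance, so 4 libraries were simulated 100 times with the spread of the residual of the additive model in each expression decile, without any effect and with a TNF effect only. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, median-ratio and upper-quartile scaling, rescaling without the 50 most abundant genes, summed transcripts, calls at 1.5-fold and 3-fold, list means, correlations over called genes only, and removal of trends over 20 length bins and 20 GC bins, which could be run on 13347 genes. The steps were tested on simulated data for the comparison of TNF with none in macrophages alone, over 13686 genes with a noise SD of 0.3: 98% of genes changed 4-fold were called, 17% of those changed 1.5-fold and 0.882% of unchanged genes were called higher. That noise lies below the residual spread of these libraries, 0.349 to 0.769 over the expression deciles. These shares are therefore no estimate of false calls in the real data, where unchanged genes may be called more often. In that simulation 4% of unchanged lists stood apart. Noise was drawn independently for each gene, so this share follows from the percentile rule itself. It does not show how often lists of genes that vary together stand apart. In the real libraries most of the 29 pathway lists stood apart in both fibroblast comparisons. Coordinates are those of GRCh37 in the GENCODE 44 annotation mapped to that build. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.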

Results

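Gene expression was compared in 4 macrophage libraries: macrophages cultured alone, macrophages under synovial fibroblasts in a transwell insert, macrophages given TNF, and macrophages given both. TNF is an inflammatory cytokine of the arthritic joint, and the series asks how synovial fibroblasts modulate the macrophage response to it. Each group holds 1 library, so no difference below has a replicate check, and "higher" and "lower" refer to a difference of at least 1 in log2(FPKM + 1). In the order given, 12636, 12598, 12542 and 12714 genes reached 1 FPKM, the median over the 13686 analysed genes was 37.6, 37.6, 37.8 and 37.5 FPKM, and the 50 most abundant genes held 31.0%, 28.5%, 27.3% and 29.1% of all FPKM. Depth behind single values is unknown.

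In macrophages cultured alone, TNF was accompanied by higher expression of inflammatory chemokines, NF-kB targets and metal-binding proteins, and by lower expression of MHC class II genes and several, but not all, scavenger receptors. CXCL5, a neutrophil-attracting chemokine, stood at 2.88 FPKM without and 3398 FPKM with TNF (log2 difference 9.78), IL1B, the gene of interleukin-1 beta, at 28.5 and 4676 FPKM (7.31), and MMP9, a matrix-degrading protease, at 188 and 12378 FPKM (6.04). IDO1, a tryptophan-degrading enzyme, was listed at 0 without TNF and at 838 FPKM with it. FOLR2, a folate receptor of tissue macrophages, went from 2986 to 1.8 FPKM (-10.06), the growth factor gene IGF1 from 317 to 0.04 FPKM (-8.26), and the scavenger receptor gene MSR1 from 444 to 2.22 FPKM (-7.11). Over all genes 1815 were higher and 1866 lower.

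Of the 30 NF-kB and TNF target genes, 24 were higher with TNF and 0 lower (median 2.89, percentile 100), among them TNFAIP6 (6.35 and 1000 FPKM), TNFAIP3 (61.2 and 680 FPKM) and NFKBIA (488 and 5129 FPKM), an inhibitor of NF-kB. Among 44 inflammatory cytokine and chemokine genes 31 were higher and 2 lower (median 2.49, percentile 100), with CXCL13 listed at 0 and 300 FPKM, CCL19 at 0 and 431 FPKM, and IL8 at 35.0 and 2030 FPKM. The TNF gene itself differed little, at 29.5 and 36.0 FPKM, and so did IL6, at 3.53 and 4.24 FPKM. Of 31 genes of the interferon-gamma type, 19 were higher and 1 lower (median 1.5, percentile 100), including SOCS1 (2.19 and 98.1 FPKM) and CD274 (6.24 and 221 FPKM), which encodes the checkpoint ligand PD-L1. Type I interferon-stimulated genes went otherwise: 3 of 46 were higher and 7 lower (median -0.14, percentile 3.47), IFIT1 standing at 374 and 121 FPKM. On summed transcripts that median was -0.23, at percentile 0.35. IFNB1, the interferon-beta gene, was listed at 0 in all 4 libraries. In the list of 21 interferons, receptors and regulators, the 14 measured members were receptors and regulators only. Of these 6 were higher and 1 lower (median 0.53, percentile 98.2), SOCS3 at 13.01 and 927 FPKM among them. The interferon genes IFNB1, IFNA1, IFNA2 and IFNG were under 1 FPKM in all 4 libraries, and IFNL1, IFNL2 and IFNL3 were absent under those symbols.

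Of 28 alternative activation and scavenger genes, 16 were lower with TNF and 6 higher (median -2.20, percentile 0). The mannose receptor gene MRC1 stood at 705 and 15.1 FPKM (-5.46), whereas the chemokine gene CCL18 stood at 30.4 and 3088 FPKM (6.62). The scavenger receptor gene MARCO was higher, at 55.5 and 138 FPKM (1.30), and CD163 was not called, at 2738 and 2481 FPKM. VSIG4, a complement receptor, was listed at 362 and 0 FPKM, and its difference on summed transcripts was -1.54. Of 15 MHC class II presentation genes, 12 were lower and 1 higher (median -1.39, percentile 0), with CIITA, the master regulator of the class II genes, at 291 and 81.0 FPKM and HLA-DRA at 32293 and 15699 FPKM. Among cell type markers, those of dendritic cells (2 higher and 5 lower of 8, median -1.68, percentile 0.02) and macrophages (1 and 5 of 14, median -0.53, percentile 0.24) also stood below random lists, and those of monocytes above (6 and 3 of 13, median 0.86, percentile 99.78). Lists share members, so they are not separate evidence. All 14 macrophage markers, 5 of 12 dendritic cell markers and 17 of 28 scavenger genes also belong to another list. Fibroblast markers, in the absence of fibroblasts, were higher with TNF in 6 of 26 and lower in 1 (median 0.34, percentile 98.3, but 96.1 with a filter at 5 FPKM). GAS6, a bridging molecule in the uptake of dying cells, went from 326 to 5.74 FPKM (-5.60), and its receptor gene MERTK stood at 117 and 124 FPKM. The STAT3 and IL-6 response list (10 higher and 3 lower of 19, median 1.25, percentile 99.99) and the matrix protease and matrix remodelling list (8 higher and 4 lower of 24, median 0.51, percentile 99.45) also stood apart. So did the prostaglandin E2 and cyclic AMP response list, with 16 higher and 4 lower of 27 (median 1.67, percentile 100), although its median was 1.05 on summed transcripts. Metallothionein genes reached the highest differences of all, MT1G being listed at 0 and 18873 FPKM, but these near-identical genes can share reads, so their individual values are uncertain.

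**Figure D1:**
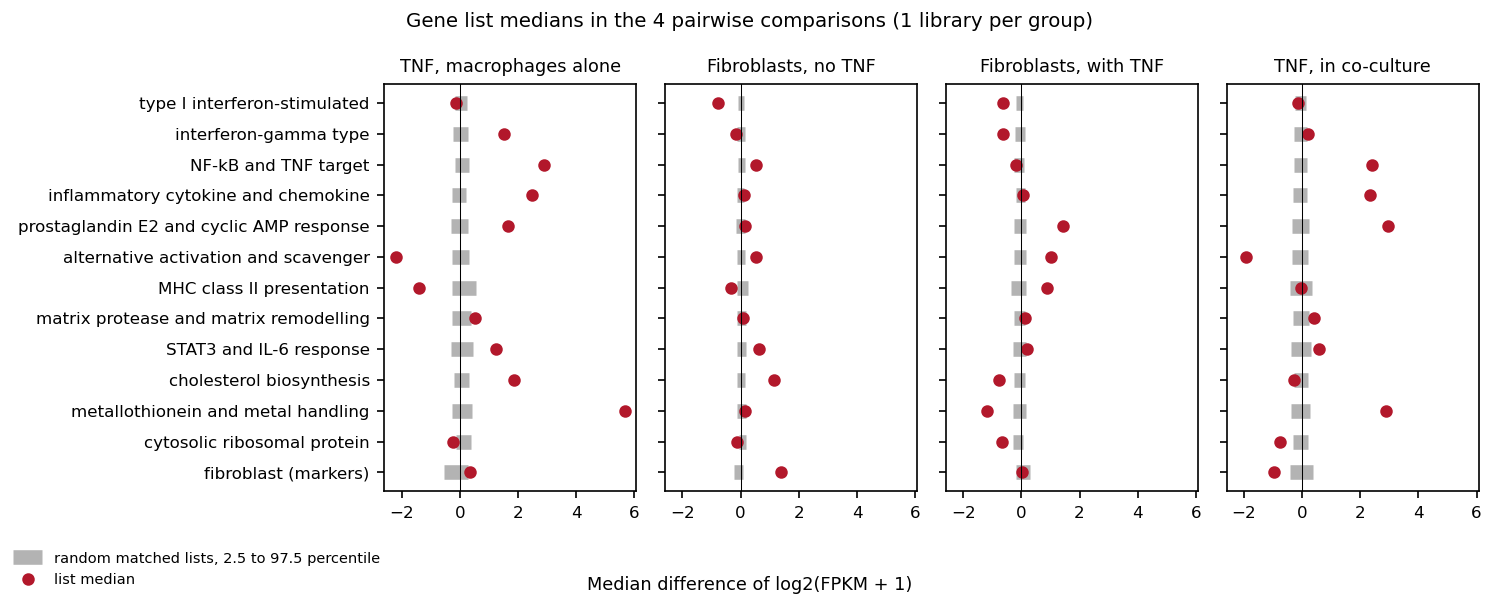
Median difference of log2(FPKM + 1) of 13 gene lists (red points) in each of the 4 pairwise comparisons, with the range of random lists matched on expression outside which a list is said to stand apart (grey bars); each comparison rests on 1 library per group. Type I interferon-stimulated genes lie at -0.79 and -0.64 in the fibroblast comparisons without and with TNF, and the prostaglandin E2 and cyclic AMP list lies at 1.42 with TNF.

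Without TNF, the type I interferon-stimulated list stood below random lists in macrophages under fibroblasts against macrophages alone. The scavenger, STAT3-type and monocyte lists stood above them. Of 46 type I interferon-stimulated genes 18 were lower and 0 higher (median -0.79, percentile 0). IFI6 stood at 2732 FPKM alone and 538 FPKM in co-culture (-2.34), ISG15, a ubiquitin-like protein, at 597 and 145 FPKM (-2.03), CXCL10, a T cell-attracting chemokine, at 89.8 and 22.6 FPKM (-1.94), IFIT1 at 374 and 103 FPKM (-1.86) and MX1 at 399 and 188 FPKM (-1.08). CXCL9 was at 3.43 FPKM alone and listed at 0 in co-culture. The interferon-gamma type list had 4 higher and 4 lower of 31 (median -0.15, percentile 0.55), but its mean was 0.09 and its median on summed transcripts was -0.07, at percentile 6.93. FCGR1A, a high-affinity antibody receptor with near-identical copies, stood at 8.58 and 211 FPKM. In this comparison 658 genes were higher and 542 lower.

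SOCS3, a feedback inhibitor of STAT3 signalling, stood at 13.01 FPKM alone and 309 FPKM in co-culture (4.47), and PIM1, a kinase downstream of STAT3, at 60.3 and 592 FPKM (3.27). Of 19 STAT3 and IL-6 response genes 6 were higher and 0 lower (median 0.62, percentile 100). IL6 stood at 3.53 and 58.8 FPKM (3.72) and CXCL6 at 3.92 and 45.1 FPKM (3.23), and 11 of 44 cytokine and chemokine genes were higher and 5 lower (median 0.12, percentile 97.8, and percentile 96.5 on summed transcripts). Among 28 alternative activation and scavenger genes 11 were higher and 0 lower (median 0.55, percentile 100), including LYVE1, a hyaluronan receptor, at 12.9 and 953 FPKM (6.10) and F13A1, coagulation factor XIII, at 3529 and 19184 FPKM (2.44). PLTP, a phospholipid transfer protein, stood at 75.0 and 2852 FPKM (5.23), ENPP2, which makes lysophosphatidic acid, at 5.4 and 602 FPKM (6.56), and GAS6 at 326 and 895 FPKM (1.45). Of 13 monocyte markers 9 were higher and 0 lower (median 1.68, percentile 100), S100A8 standing at 120 and 1173 FPKM, while CD14 was called on its main transcript (3.36) but not on the sum (0.87). T cell markers stood below random lists, with 1 higher and 3 lower of 12 (median -0.63, percentile 0.2, but 2.69 with a filter at 5 FPKM). NF-kB and TNF targets had 7 higher and 1 lower of 30 (median 0.52, percentile 100), MHC class II genes 0 of 15 called (median -0.32, percentile 0), and the prostaglandin E2 and cyclic AMP list 7 higher and 1 lower of 27 (median 0.14, percentile 97.54). The prostaglandin E2 and cyclic AMP list stood apart here in only 6 of 11 settings, with values from 0.06 to 0.47.

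Fibroblast transcripts moved with this comparison. Of 26 fibroblast markers 17 were higher in the co-cultured library without TNF and 1 lower (median 1.39, percentile 100). COL1A1 stood at 10.5 FPKM alone and 32.2 FPKM in co-culture, COL1A2 at 12.5 and 42.5 FPKM, COL3A1 at 6.58 and 48.6 FPKM and the proteoglycan gene DCN at 1.34 and 14.6 FPKM. MMP1, a collagenase, was at 0.87 and 13.6 FPKM, and MMP3 was listed at 0 and 10.4 FPKM, within a matrix protease list that did not stand apart (5 higher, 3 lower of 24, median 0.10). The single genes of this comparison depend on the transcript chosen: of the 10 highest, 3 kept their call on summed transcripts (ENPP2, LYVE1 and PLTP), and of the 10 lowest, 4 did (PDE4DIP, FABP4, PPP1R13L and SDCBP2, whose main transcripts were all listed at 0 in co-culture). SDCBP, lowest of all at 1090 and 2.97 FPKM (-8.10), differed by 0.23 on the sum, and CD200R1, highest of all with values of 0 and 211 FPKM, by 0.41.

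**Figure D2:**
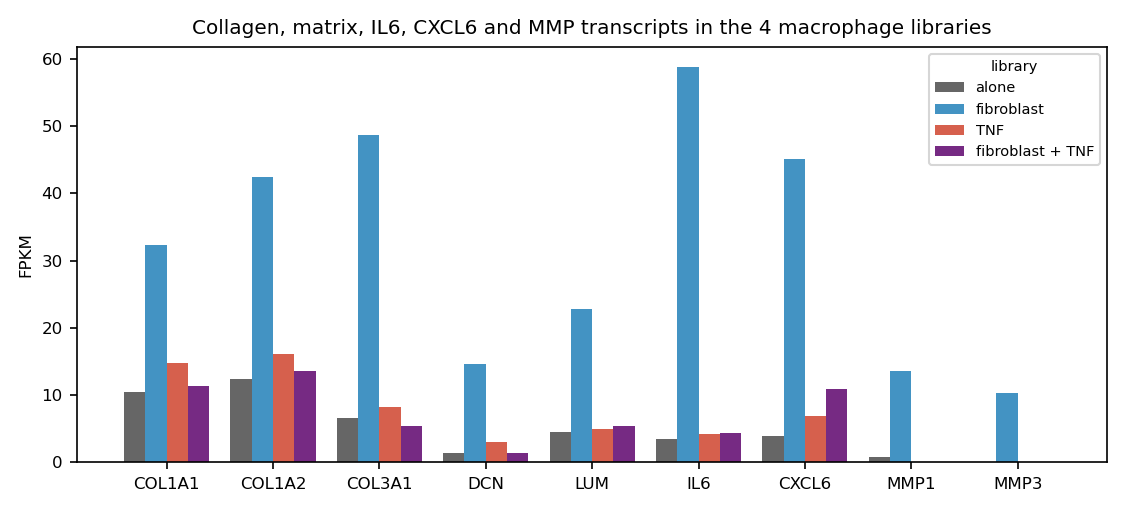
FPKM of 9 genes typical of fibroblasts or high in the co-cultured library, in each of the 4 macrophage libraries (bars, 1 library each, axis from 0). COL1A1 reaches 32.2 FPKM in the co-cultured library without TNF and 10.5, 14.8 and 11.4 FPKM in the libraries of macrophages alone, TNF, and both.

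With TNF present in both cultures, interferon-type lists stood below random lists with fibroblasts against none. The prostaglandin-response, scavenger and MHC class II lists stood above them. This comparison is the closest to the question of the series. CXCL10 stood at 117 FPKM with TNF alone and 18.3 FPKM with fibroblasts as well (-2.61), and CXCL9 at 11.1 FPKM and listed at 0. Of 46 type I interferon-stimulated genes 12 were lower and 1 higher (median -0.64, percentile 0), IFIT1 at 121 and 59.7 FPKM and MX1 at 308 and 193 FPKM, the latter short of a call. IFI27 stood at 144 and 1.81 FPKM (-5.69, and -3.28 on summed transcripts). Of 31 interferon-gamma type genes 8 were lower and 1 higher (median -0.63, percentile 0). Over all genes 1181 were higher and 896 lower.

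Of 27 prostaglandin E2 and cyclic AMP response genes 17 were higher and 3 lower (median 1.42, percentile 100). The epidermal growth factor family genes HBEGF and EREG stood at 5.77 and 327 FPKM (5.60) and at 53.1 and 1217 FPKM (4.49), THBS1, the matrix protein thrombospondin, at 240 and 7753 FPKM (5.01), and PTGS2, which encodes cyclooxygenase-2, at 10.8 and 217 FPKM (4.20). Cytokine genes went both ways, with 15 higher and 12 lower of 44 (median 0.05, percentile 83.4). CCL24 stood at 11.4 and 1373 FPKM (6.79), CCL22 at 7.96 and 536 FPKM (5.90) and IL8 at 2030 and 6671 FPKM (1.72), whereas CXCL13 stood at 300 and 2.14 FPKM (-6.58), CCL19 at 431 and 18.3 FPKM (-4.48) and IL10 at 838 and 170 FPKM (-2.29). IL1B (4676 and 8125 FPKM), TNF (36.0 and 32.5 FPKM) and IL6 (4.24 and 4.39 FPKM) were not called. The NF-kB and TNF target list did not stand apart (2 higher and 4 lower of 30, median -0.19, percentile 7.24).

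Of 28 alternative activation and scavenger genes 15 were higher and 5 lower (median 1.03, percentile 100). MRC1 stood at 15.1 and 424 FPKM (4.73), while MARCO, another scavenger receptor, stood at 138 and 2.3 FPKM (-5.40) and CD163 at 2481 and 1780 FPKM. All 7 called MHC class II genes of 15 were higher (median 0.87, percentile 100), with CIITA at 81.0 and 226 FPKM (1.47) and HLA-DRA at 15699 and 39421 FPKM (1.33). Dendritic cell markers had 4 higher and 0 lower of 8 (median 0.73, percentile 99.33), and macrophage markers 3 higher and 6 lower of 14 (median -0.64, percentile 0). GAS6 (5.74 and 62.2 FPKM, 3.23) and MERTK (124 and 303 FPKM, 1.28) were both higher. EMR3, an adhesion receptor of myeloid cells, had the highest difference, at 0.89 and 635 FPKM (8.39), and HSD11B1, which regenerates cortisol, was among the lowest at 502 and 3.58 FPKM (-6.78). The matrix protease list had 6 higher and 2 lower of 24 (median 0.14, percentile 97.7, but 0.10 and percentile 94.1 on summed transcripts), ADAM8 at 38.0 and 744 FPKM, and the STAT3 and IL-6 response list 5 higher and 4 lower of 19 (median 0.18, percentile 97.9). The STAT3 and IL-6 response list stood apart here in 8 of 11 settings, with values from 0.09 to 0.23. Interferon receptors and regulators had 0 of 14 called (median -0.16, percentile 22.9). Fibroblast markers did not stand apart here (2 higher, 3 lower of 26, median 0.02, percentile 61.9, and -0.03 on summed transcripts), and COL1A1 stood at 14.8 and 11.4 FPKM. Markers of natural killer cells did, with 4 lower of 8 (median -1.27, percentile 0, and -0.69 on summed transcripts), NKG7 at 6328 and 1786 FPKM among them. Of the 10 highest and 10 lowest genes, 7 and 7 kept their call on summed transcripts, and the lowest by transcript did not: GK, listed at 191 and 0 FPKM, and APP, at 153 and 0.02 FPKM, differed by 0.02 and 1.86 on the sum.

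**Figure D3:**
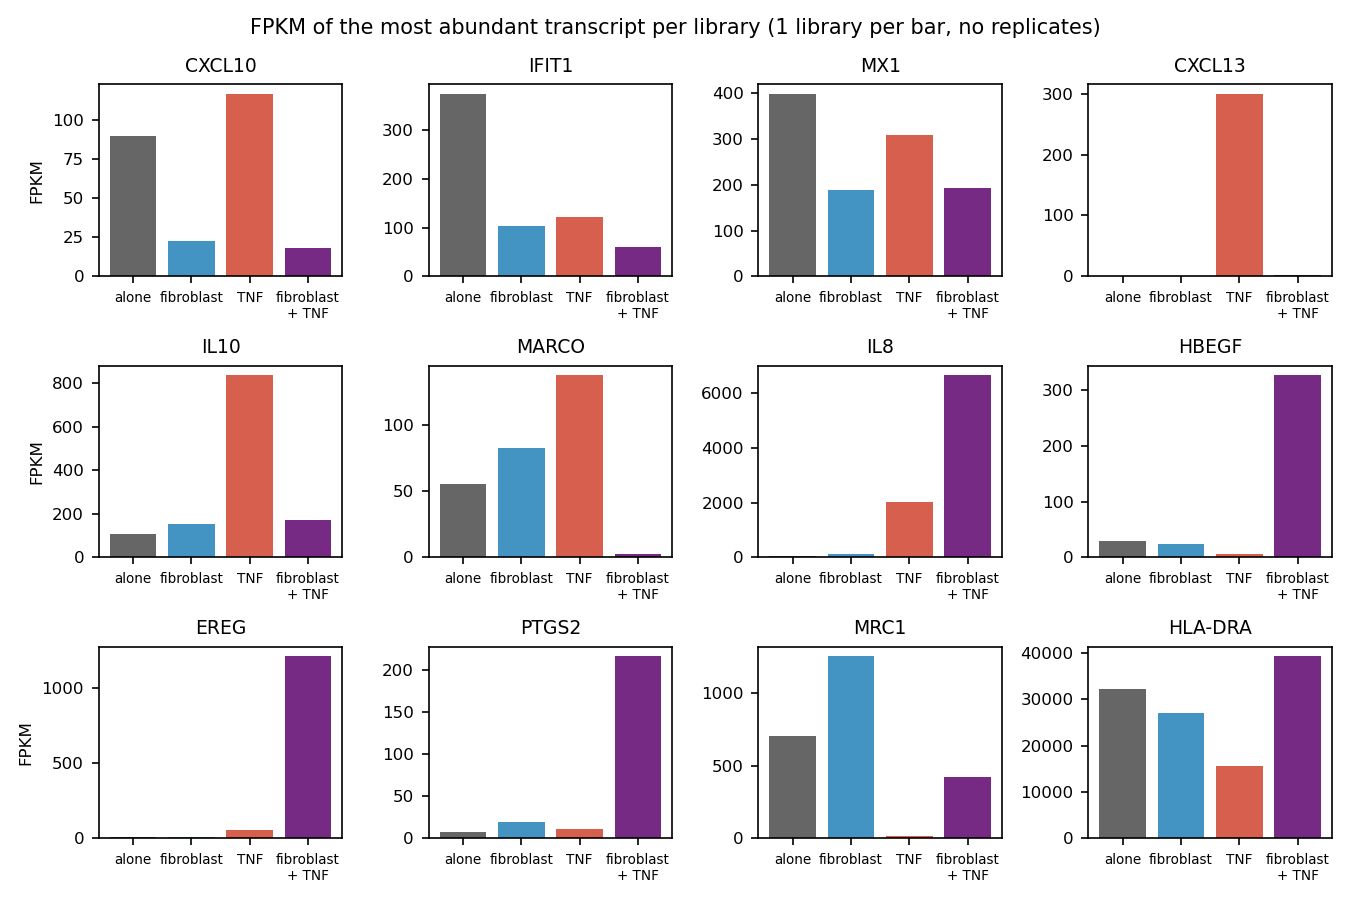
FPKM of the most abundant transcript of 12 genes in each of the 4 libraries (bars, 1 library each, axes from 0 and of different height). HBEGF reaches 327 FPKM and EREG 1217 FPKM in the library with both fibroblasts and TNF, where CXCL10 stands at 18.3 FPKM and IL10 at 170 FPKM.

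In co-cultured macrophages, TNF was accompanied by much of the inflammatory program seen without fibroblasts. CXCL5 stood at 12.7 and 8182 FPKM (9.22), IL1B at 53.2 and 8125 FPKM (7.23), MMP9 at 200 and 21390 FPKM (6.73) and EREG at 9.9 and 1217 FPKM (6.80), while FOLR2 stood at 3338 and 4.36 FPKM (-9.28), LYVE1 at 953 and 1.07 FPKM (-8.85) and F13A1 at 19184 and 86.1 FPKM (-7.78). There were 1778 higher and 1585 lower genes, against 1673 and 1753 after rescaling without the 50 most abundant genes. Of 30 NF-kB and TNF targets 24 were higher and 2 lower (median 2.42, percentile 100), of 44 cytokine and chemokine genes 28 and 5 (median 2.34, percentile 100), of 27 prostaglandin E2 and cyclic AMP genes 20 and 2 (median 2.96, percentile 100), and of 28 alternative activation and scavenger genes 7 and 18 (median -1.92, percentile 0). The interferon-gamma type list had 14 higher and 5 lower of 31 (median 0.19, percentile 98.3). Neither the type I interferon-stimulated genes (3 higher, 5 lower of 46, median -0.15) nor the MHC class II genes (2 and 2 of 15, median -0.02, and 0.01 on summed transcripts) stood apart. Macrophage markers had 3 higher and 8 lower of 14 (median -1.64, percentile 0) and monocyte markers 6 and 2 of 13 (median 0.90, percentile 99.94). Fibroblast markers were lower with TNF in 13 of 26 and higher in 2 (median -0.95, percentile 0.01), and IL6 stood at 58.8 FPKM without and 4.39 FPKM with TNF.

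Across genes, the TNF effect without and with fibroblasts, which share no library, had a Pearson r of 0.664 and a Spearman rho of 0.587 over 13686 genes, which are not independent replicates. Of the 1815 genes higher with TNF in macrophages alone, with a median difference of 1.85, 1074 (59.2%) were also higher with TNF in co-culture and 66 were lower there, and their median difference in co-culture was 1.29. Of the 1866 lower genes (median -1.71), 851 (45.6%) were also lower in co-culture, where the median was -0.88. Genes chosen in co-culture had smaller medians in macrophages alone in the same way, 1.36 against 1.87 for higher and -1.10 against -1.59 for lower genes, so part of the smaller value follows from choosing genes by size. The fibroblast effects without and with TNF had an r of 0.00498 and a rho of 0.0425, with 111 genes higher in both (56.8 if independent), 97 lower in both (35.5) and 201 called in opposite directions (89.8).

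Among the 1815 genes higher with TNF alone, 459, or 25.3% (95% Wilson interval 23.3 to 27.3), were lower and 137, or 7.55% (6.42 to 8.86), higher when fibroblasts were present with TNF. Those comparisons share the TNF library: simulated libraries gave 36.4% and 1.69% with no effect at all, and 20.05% and 5.15% with a TNF effect only. The simulated spread, the residual of the additive model, also contains any real difference between the TNF effects with and without fibroblasts. Noise and the simulated shares may therefore be overstated, and they cannot decide whether the observed shares exceed chance. Of the 1866 genes lower with TNF alone, 577, or 30.9% (28.9 to 33.1), were higher and 63, or 3.38% (2.65 to 4.30), lower with fibroblasts, against 33.2% and 1.57% simulated with no effect and 18.96% and 3.90% with a TNF effect only. The simulations called other numbers of genes than the 1815 and 1866 observed, 1238.5 higher and 1231 lower with no effect and 2426.5 and 2466 with a TNF effect only (medians over simulations), so their shares are no exact counterpart. The intervals cover counting of genes only.

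The difference between the TNF effects with and without fibroblasts uses all 4 libraries. It was higher for 1557 and lower for 1271 genes, led by EMR3 (8.44), CCL24 (6.96), CD226 (6.89) and HBEGF (5.93) on one side and by ENPP2 (-8.29), PLTP (-8.15) and HSD11B1 (-7.78) on the other. MHC class II genes (10 higher and 0 lower of 15, median 1.37) and prostaglandin E2 and cyclic AMP genes (13 and 5 of 27, median 0.71, and 1.48 on summed transcripts) stood above random lists. NF-kB targets (2 higher and 9 lower of 30, median -0.62), interferon-gamma type genes (1 and 10 of 31, median -0.54) and cytokine genes (15 and 17 of 44, median -0.55) stood below. Type I interferon-stimulated genes had a median of 0.03 at percentile 93.7: their median fibroblast effects were similar without and with TNF (-0.79 and -0.64). Of the 10 highest and 10 lowest genes of this difference, 8 and 5 kept their call on summed transcripts.

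**Figure D4:**
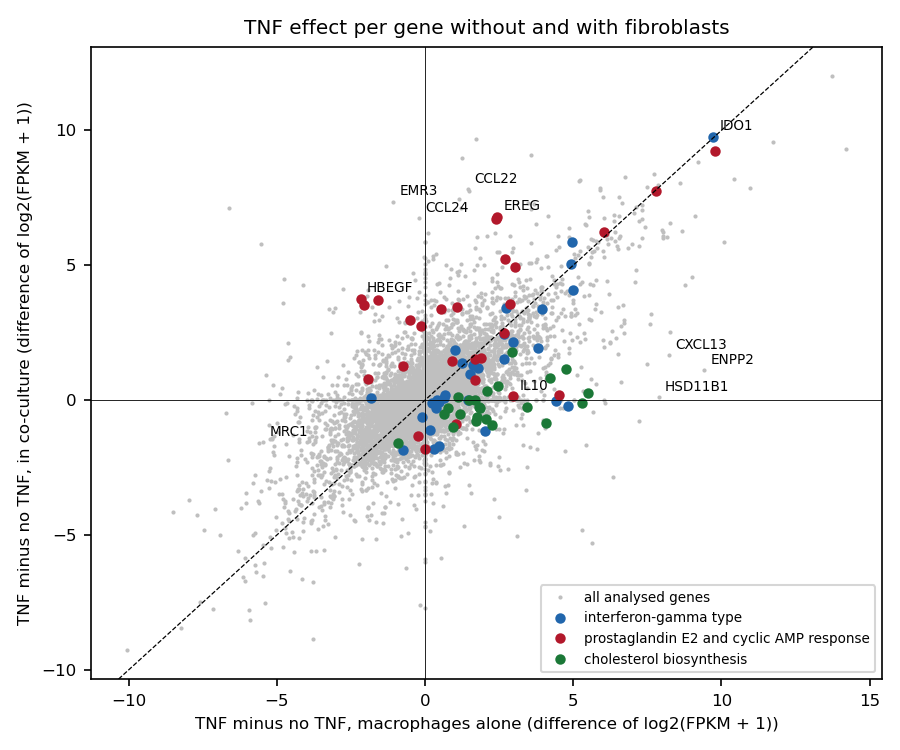
Difference of log2(FPKM + 1) between TNF and no TNF for each of 13686 genes, in macrophages alone (horizontal) and in co-culture (vertical), with 3 gene lists in colour and the line of equal effects dashed. Across genes r is 0.664, and HBEGF lies at -2.17 alone and 3.76 in co-culture.

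In GRCh37, with all of the following annotated as protein-coding genes, CXCL10 lies on chromosome 4 from 76942271 to 76944650, CXCL9 on chromosome 4 from 76922428 to 76928662, EREG on chromosome 4 from 75230862 to 75254466 and IL8 (CXCL8) on chromosome 4 from 74606236 to 74609433. IFIT1 lies on chromosome 10 from 91152303 to 91166244, HBEGF on chromosome 5 from 139712428 to 139726188, PTGS2 on chromosome 1 from 186640923 to 186650054, and IL10 on chromosome 1 from 206940947 to 206947886. EMR3 (ADGRE3) lies on chromosome 19 from 14729929 to 14800839, CCL22 on chromosome 16 from 57392695 to 57400101, CIITA on chromosome 16 from 10960079 to 11036878, MRC1 on chromosome 10 from 18098352 to 18200091, and IL6 on chromosome 7 from 22765503 to 22771621.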

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

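Of the tests given here, those of fibroblast carry-over in the library without TNF, of the same carry-over with TNF, and of dilution by fibroblast RNA, together with the choice to correct for length and GC content, were chosen only after the results were seen. Each difference below rests on 1 library per condition, and the difference between the effects was not tested.

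Of 26 fibroblast markers 17 were higher and 1 lower in the co-cultured library without TNF (median 1.39), and the marker list went opposite ways with TNF, 0.34 in macrophages alone (percentile 98.3), where no fibroblasts were present, and -0.95 in co-culture. The tables argue against scaling of the library, since the median was 1.38 under median-ratio scaling. Fibroblast cells or RNA carried into that library, although the insert is made to keep the cell layers apart, and expression by the macrophages cannot be told apart: the 23 markers under 20 FPKM in macrophages alone had a median difference of 1.42, but they are part of the pattern itself and both would raise them. Of the 26 markers, 3 were at 20 FPKM or more in macrophages alone and were left out of that test, and the summed FPKM of the other 23 was 59.2 in macrophages alone, 228 in co-culture, 162 with TNF and 99.5 with both. The same markers differed by 0.0300 with TNF present, which argues against the same carry-over there, and whether macrophages made the IL6, CXCL6, MMP1 and MMP3 of the library without TNF stays open.

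Of 46 type I interferon-stimulated genes 12 were lower and 1 higher in co-culture with TNF (median -0.64). Median-ratio scaling left -0.59 and removal of length and GC trends left -0.62, so the tables argue against both as the whole cause. Macrophage markers had a median of -0.64 (3 higher and 6 lower of 14), as dilution by fibroblast RNA would give. Fibroblast markers under 20 FPKM in macrophages alone differed by 0.0300, which argues against dilution. MHC class II genes differed by 0.87, but this cannot decide. That list also moved with TNF in macrophages alone (median -1.39), so it is no neutral reference for macrophage RNA. An effect of the fibroblasts on the macrophages may underlie the pattern as a hypothesis, found in and weighed on the same libraries. A difference between cultures or donors was not tested and stays open.

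Cytosolic ribosomal protein genes had a median below 0 in the library with both TNF and fibroblasts, -0.66 against TNF alone (0 of 34 above 0, but 2 called lower) and -0.75 against co-culture without TNF (6 called lower). The list also stood below random lists, by less and with 0 of 34 called, in the comparisons without that library. Its median was -0.24 with TNF in macrophages alone (percentile 0.28) and -0.13 with fibroblasts without TNF (percentile 0.07). The median was -0.55 once length and GC trends were removed and -0.63 after rescaling without the 50 most abundant genes, values that argue against both as the whole cause. A difference in RNA handling between the cultures was not tested, and neither was a biological explanation.

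Opposite effects in the other factor's presence were seen for 3 further lists. The fibroblast effect on MHC class II genes was -0.32 without and 0.87 with TNF. On cholesterol biosynthesis genes it was 1.16 and -0.77. The TNF effect on TGF-beta response genes was -0.89 alone and 0.89 in co-culture (0.55 in co-culture on summed transcripts).

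Over all analysed genes, 159 were called in opposite directions by TNF and 201 by fibroblasts, and 94 named genes were looked at singly. If the calls were independent, 452.6 and 89.8 would be opposite. Opposite TNF calls were thus fewer, and opposite fibroblast calls more, than independence would give. The excess for fibroblasts was not particular to opposite calls. Genes higher in both fibroblast comparisons numbered 111 (56.8 if independent), and those lower in both 97 (35.5). Opposite TNF effects, alone and then in co-culture, were EMR3 -1.09 and 7.36, HBEGF -2.17 and 3.76, IFI27 2.46 and -2.46 (1.57 and 0.23 on summed transcripts), MARCO 1.30 and -4.67, and RAB34 -4.55 and 1.58 (0.98 and 1.35 on summed transcripts). Opposite fibroblast effects, without and then with TNF, were CLU 1.96 and -1.12 (1.06 without TNF on summed transcripts), CXCR2P1 (a pseudogene, which can share reads with its parent) -1.97 and 2.31, ENPP2 6.56 and -1.73, HSD11B1 1.00 and -6.78 (0.81 and -6.52 on summed transcripts), MT1G 3.06 and -1.83, and SLC40A1 -1.27 and 1.37. For EMR3, HSD11B1 and CLU the smaller effect rests on low values. EMR3 stood at 3.01 and 0.89 FPKM without and with TNF in macrophages alone. Without TNF, HSD11B1 stood at 1.14 FPKM alone and 3.29 FPKM with fibroblasts, and one of the values of CLU was also low (0.32 and 4.14 FPKM). The gene PLTP was opposite in both respects, with TNF effects of 3.11 and -5.04 and fibroblast effects of 5.23 and -2.92. So were CD226 (TNF -2.78 and 4.11, fibroblasts -1.09 and 5.80), IL12RB2 (TNF 5.44 and -1.66, fibroblasts 3.69 and -3.41), SERINC2 (TNF -4.76 and 4.47, fibroblasts -2.63 and 6.60, with 1.36 for TNF in co-culture and -1.03 for fibroblasts without TNF on summed transcripts), SDCBP2 (TNF -4.11 and 4.25, fibroblasts -4.11 and 4.25, with -2.37 for TNF alone and 2.51 for fibroblasts with TNF on summed transcripts) and SMN1 (which shares reads with its near-identical copy; TNF -4.78 and 3.58, fibroblasts -3.89 and 4.48, with 1.99 for TNF in co-culture and -2.18 for fibroblasts without TNF on summed transcripts).

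For 5 more genes opposite in both respects, at least 1 of these effects lost its call or turned on summed transcripts. CDH23 had TNF effects of -3.24 and 3.39 (0.59 and 1.11 summed) and fibroblast effects of -2.24 and 4.39 (-0.59 and -0.07 summed). The TNF effects of CMTM1 were -4.62 and 2.12 (-4.66 and -1.61 summed) and its fibroblast effects -4.62 and 2.12 (0.05 and 3.10 summed). GK had TNF effects of 5.63 and -5.32 (4.15 and 2.24 summed) and fibroblast effects of 3.36 and -7.58 (1.93 and 0.02 summed). HAS3 had TNF effects of -2.18 and 3.25 (-2.18 and 0.04 summed) and fibroblast effects of -4.07 and 1.37 (-0.42 and 1.81 summed). LMAN2L had TNF effects of 5.28 and -4.81 (-0.08 and 0.25 summed) and fibroblast effects of 4.81 and -5.28 (-0.20 and 0.13 summed). The main transcripts of CMTM1, CXCR2P1, GK, HAS3, IL12RB2, LMAN2L, MT1G, SDCBP2 and SERINC2 were listed at 0 in at least 1 library, so the size of those differences depends on the pseudocount and is no fold.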

How the results depend on the processing

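The correction for length and GC content was chosen after the data were seen, the other settings before, but the most abundant transcript was settled on as the main value after results on summed transcripts had also been seen. Every comparison rests on 1 library per group, so no setting replaces a replicate, and depth per gene is unknown. No paired analysis was possible because each group has 1 library and no result comes from a test. Across alternatives, 2463 results for named genes kept their direction and side of the call, 14 gained a call, 41 lost it and 12 reversed. For gene lists the numbers were 1880, 40, 65 and 10. The gene totals include settings that could not change the outcome: the filters leave a gene's difference as it is, and other call sizes cannot turn its direction. Summed transcripts alone gave all 12 gene reversals and 16 of the 41 lost calls, with 201 gene results kept. The type I interferon-stimulated list stood apart in all 11 settings in both fibroblast comparisons. With TNF in macrophages alone, the median difference of all genes was -0.01, and it moved by over 0.1, to -0.12 under upper-quartile scaling and to -0.18 under rescaling without the 50 most abundant genes.

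Which direction had more calls depended on the setting for both TNF comparisons: with TNF in macrophages alone there were 1534 higher and 1486 lower genes with a filter at 5 FPKM and 1804 and 1710 without length and GC trends, and with TNF in co-culture 1673 and 1753 after rescaling without the 50 most abundant genes but 1861 and 1452 under median-ratio scaling. In macrophages alone the counts leaned further to lower genes under other scalings. They were 1582 higher and 2199 lower after rescaling without the 50 most abundant genes, and 1673 and 2063 under upper-quartile scaling. Counts of calls follow the size asked for. With TNF in macrophages alone, 2811 higher and 3041 lower genes were called at 1.5-fold, and 1095 and 1043 at 3-fold. For fibroblasts without TNF the counts were 1257 and 1180, then 291 and 234. For fibroblasts with TNF they were 2031 and 1961, then 580 and 371. For TNF in co-culture they were 2673 and 2870, then 1087 and 795, and for the difference of TNF effects 2612 and 2492, then 825 and 631. A pseudocount of 5, which shrinks genes of low value, left 1147 lower genes with TNF alone, 349 higher and 204 lower with fibroblasts without TNF, 668 and 475 with TNF, 949 lower with TNF in co-culture, and 878 higher and 763 lower for the difference. A filter at 5 FPKM, with fewer genes, left 350 lower with fibroblasts without TNF. On list means, fewer pathway lists stood above random lists than on medians: 7 for fibroblasts with TNF and 4 for the difference of TNF effects. The cause was not tested.

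Of TNF-higher genes, the share lower with fibroblasts was 19.9% with a pseudocount of 5, 22.3% with a filter at 5 FPKM, 30.6% at 1.5-fold and 17.9% at 3-fold, and the share higher was 9.28% and 6.04% with pseudocounts of 0.1 and 5, 11.9% at 1.5-fold and 4.66% at 3-fold. Of TNF-lower genes, the share lower was 5.79% and 2.09% with those pseudocounts, 7.60% at 1.5-fold and 1.44% at 3-fold, and the share higher was 36.8% and 25.5%, 33.6% with a filter at 5 FPKM, 27.97% without the 50 most abundant genes, 35.9% at 1.5-fold and 23.7% at 3-fold. The correlation of the fibroblast effects stayed near 0: r was 0.0155 and 0.000381 with pseudocounts of 0.1 and 5, 0.0207 on summed transcripts, 0.00988 without length and GC trends, -0.000474 with a filter at 5 FPKM and -0.0110 over called genes. The cause was not tested.

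Reversed list values on means were 0.0907 for interferon-gamma type genes with fibroblasts without TNF, and, with fibroblasts and TNF, 0.0755 for costimulation and -0.13 for complement genes; their members go both ways. With no filter, which adds members under 1 FPKM in all 4 libraries, the medians were 0 for the matrix protease list (fibroblasts with TNF), the glucocorticoid list (TNF in co-culture), the platelet list (both TNF comparisons) and the erythroid list (TNF alone, fibroblasts without TNF and the difference).

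Summing transcripts, which removes shifts between transcripts of a gene, gave for fibroblasts without TNF 0.0500 for CMTM1, -0.0111 for CREM, 0.27 for MFSD11 and PTAFR (0.271 and 0.272), 0.23 for SDCBP and -0.31 for TRPT1. For fibroblasts with TNF it gave 1.86 for APP and 0.0239 for GK, for TNF in co-culture 1.30 for APP, and for the difference 1.57 for APP, 0.34 for LMAN2L and -0.64 for SDCBP. Called genes were largely shared: of 1181 higher with fibroblasts and TNF, 1015 were also among the 1093 called on sums, and of 658 higher with fibroblasts without TNF, 526 among 564.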

Other observations

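Of 23 cholesterol biosynthesis genes 19 were higher with TNF in macrophages alone and 0 lower (median 1.85, percentile 100), and 15 were higher with fibroblasts without TNF (1.16, percentile 100). With TNF present, 7 were lower with fibroblasts and 0 higher (-0.77, percentile 0). With TNF in co-culture 2 were higher and 2 lower, and the list did not stand apart (-0.27, percentile 3.14). SQLE, which encodes squalene epoxidase, stood at 17.6, 195, 315 and 107 FPKM in macrophages alone, with fibroblasts, with TNF and with both. The LXR target and lipid handling list stood below random lists with fibroblasts both without TNF (3 higher, 6 lower of 22, median -0.31, percentile 0.01) and with it (1 and 8, median -0.62, percentile 0) and did not stand apart with TNF in co-culture (6 and 4, median 0.22, percentile 96.2), APOE standing at 1538, 164, 2323 and 802 FPKM. Glycolysis and hypoxia genes were higher with TNF in 16 of 30 and lower in 0 (median 1.20, percentile 100). Oxidative phosphorylation genes had 0 of 28 called with fibroblasts and TNF, with a median of -0.41 at percentile 0.02.

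Metallothionein and metal handling genes were higher with TNF alone in 15 of 19 (median 5.67, percentile 100) and lower with fibroblasts and TNF in 11 (median -1.19, percentile 0). HAMP, the gene of the iron hormone hepcidin, stood at 155 FPKM with TNF and 4.62 FPKM with both. Costimulation and mature dendritic cell genes were higher with TNF in 15 of 18 (median 3.96), and with fibroblasts and TNF had a median of -0.32 (percentile 1.46) but a mean of 0.08. In the apoptotic cell uptake and bridging list 9 of 19 genes were lower with TNF (median -0.88), and 4 were higher and 2 lower with fibroblasts and TNF (median 0.51, percentile 100). The TGF-beta response list had 7 higher and 0 lower of 17 with fibroblasts and TNF (median 0.53, percentile 99.99), TGFBI differing by 3.48. The immediate early list stood above random lists with fibroblasts without TNF (5 higher, 1 lower of 17, median 0.60) and with it (7 and 2, median 0.58), EGR1 standing at 136, 346, 9.37 and 173 FPKM. Complement and coagulation genes had 10 higher and 3 lower of 21 with fibroblasts without TNF (median 0.77), CFB standing at 1407 FPKM with TNF and 162 FPKM with both.

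For fibroblasts with TNF against TNF alone, the remaining lists gave these medians: prostaglandin synthesis and receptors 0.00 (percentile 66.0), MHC class I presentation -0.32 (percentile 1.86, 0 of 18 called), osteoclast differentiation 0.43 (percentile 99.99), and cell cycle -0.73 (percentile 0, 3 higher and 6 lower of 26, members at low FPKM). Glucocorticoid response genes lay at 0.03, unfolded protein and heat shock response genes at -0.07, macrophage growth factor and lysosome genes at -0.15 and housekeeping genes at -0.19, none of them standing apart. ALOX5AP, needed for leukotriene synthesis, stood at 29.4 and 1797 FPKM.

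Markers of other cells were low in most cases. With fibroblasts and TNF against TNF alone, monocyte markers had a median of 0.47 (percentile 99.87), endothelial markers lay at 0.74 (4 measured), platelet and megakaryocyte markers at 0.08, neutrophil markers at -0.21, T cell markers at -0.08 (-0.12 on summed transcripts) and B cell and plasma cell markers at -0.03 (0.25 on summed transcripts). In macrophages given TNF against those alone, T cell markers had a median of -0.94 (percentile 2.04) and B cell and plasma cell markers of -1.29 (percentile 2.16, and 3.42 on summed transcripts), with CD79A at 11.5 and 3.76 FPKM. Over 11 settings the T cell list stood apart in 7 (-1.15 to -0.23) and the B cell and plasma cell list in 3 (-1.59 to -0.59). Platelet and megakaryocyte markers, 6 of them measured, stood above random lists with TNF in macrophages alone (3 higher and 2 lower, median 1.88, percentile 99.72) and in co-culture (3 and 1, median 2.01, percentile 99.74). Erythroid markers HBA1, HBA2 and HBB were at 9.62, 7.6 and 7.18 FPKM in macrophages alone and listed at 0 in the other 3 libraries.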
